A study of Homo sapiens with 44 samples.

How the data were processed

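Gene counts were deposited as 1 table per line, and per the submitters' processing notes reads were aligned to the human hg19 (GRCh37) genome with HISAT2, handled with SAMtools, counted with Subread and compared with DESeq2, with no versions given. The values were whole numbers with a total per library of the size of a read count, and every sample column of both tables was used. Libraries were made from 500 ng total RNA with a stranded poly(A) kit, per the labels' protocols; the labels list genomic DNA as the molecule, and the protocols were followed. Estradiol was renewed with the medium every 2 days, per the labels' protocols. Genes were used by the 26364 symbols in the tables, of which 25144 matched a place in the gene order and 24504 a GC content and length in the RefSeq annotation of GRCh38.p14, which served only for names, neighbour order and composition and not for coordinates.

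Each line was analysed apart with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Libraries were scaled by TMM, genes with too few counts were removed by filterByExpr with the groups as given, and changes were tested with the quasi-likelihood F test, p-values being adjusted by the method of Benjamini and Hochberg within each comparison and genes called below 0.05. The 12 libraries at 8 h were fitted together for the comparisons of genotype, estradiol and their difference, the 14 WT libraries together for prolonged estradiol, and the 10 prolonged libraries for the log2 change per day. For prolonged estradiol the mean of the 5 day groups was compared with DMSO or estradiol at 8 h. Comparisons, lists and the rule for naming genes were fixed before the data were examined, as were 176 of the alternatives. CPM used TMM-scaled library sizes, with a prior count of 2 where logarithms were taken.

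Named genes had an adjusted p below 0.05, a mean of at least 1 CPM and no overlap between the libraries compared, where this applied, and were the 10 largest changes each way for estradiol in WT, each mutation under DMSO and prolonged estradiol against DMSO, and the 5 largest each way otherwise. For prolonged estradiol, overlap was not tested. Instead the mean log2 CPM over the days had to change in the same direction in both clones. ESR1, the list members with the smallest p, MTAP and CDKN2A, and the 10 genes with the largest change shared by both lines were added by rule. Values of GREB1, CXCL12, SUSD3, OAS1, TOP2A, BUB1B, CDC6, STC2, CCND1 and other list members in further comparisons, and the genes named for opposite effects between the lines, were chosen after values were seen. A fold against a group without counts was bounded with 3 counts over that group, and groups of 1 to 3 counts carry an exact 95% binomial interval of the counts.

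The 19 fixed lists held 319 genes: estrogen-induced and estrogen-repressed targets, G1/S, G2/M, interferon, NF-kB, mesenchymal, luminal, basal, immune and endothelial, cholesterol, unfolded protein response, hypoxia, immediate early, receptor partners, growth factors, ribosome biogenesis, p53, and androgen, progesterone and glucocorticoid targets. Lists were tested by camera with a preset correlation of 0.01 and again with the correlation estimated from the data, adjusted over the lists of a comparison. Up to 200 genes that estradiol changed most in 1 line formed further lists for the other, tested by camera without adjustment over lists. Those induced in MCF-7 with the clone as a block rose in Y537S T-47D clones (72 of 185 higher, 7 lower, 106 not called, camera p = 9.02e-18, and 0.00479 with an estimated correlation).

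Clones of the same number were taken as the same cells within a genotype. Their differences were correlated between groups of a genotype, with a median r of 0.157 in T-47D (0.0228 to 0.673) and 0.345 in MCF-7 (0.101 to 0.725). Between genotypes the medians were -0.0189 (-0.431 to 0.127) and -0.0417 (-0.127 to 0.117). In T-47D, WT values between 8 h and days were 0.0228 to 0.160, mostly within the range between genotypes. Values among the day groups alone were also low, at 0.115 to 0.240. That the same cells were used at 8 h and at days is therefore not shown for T-47D. The clone as a block was set down beforehand as a second fit for estradiol comparisons. The 176 alternatives set down and the 23 added after the data were seen were DESeq2 1.42.0, RLE scaling, no low-count filter, only the compared groups, blocks, each library left out, days 5 to 20, all 22 libraries in the fit, 5 thinnings, correction for GC content and length with a lowess span of 0.3, centring on a running median of 41 neighbouring genes, and leaving out MCF-7 libraries in doubt. Shifted neighbourhoods were those with a median log2 shift of at least 0.4 in both clones. Chance overlap was taken from list sizes and from 20 simulations of unchanged groups with the shared DMSO libraries and no clone effects.

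The edgeR and camera steps were tested on counts simulated from the libraries' means, sizes and dispersions with 200 changed genes, 100 at each fold. For estradiol in WT, edgeR recovered 57% of 2-fold and 89% of 4-fold changes in T-47D with 8 unchanged genes called, and 40% and 81% in MCF-7 with 3; with the clone as a block, and clone effects of SD 0.4 on the log2 scale simulated, it recovered 46% and 84% (10 unchanged called) and 13% and 78% (6). For Y537S it recovered 52% and 86% in T-47D (6) and 27% and 78% in MCF-7 (4), for prolonged estradiol 90% and 100% (9) and 54% and 91% (9), and for the trend 72% and 92% (10) and 23% and 78% (8). The simulation with the clone as a block took its dispersions from the fit without the block, which already held spread between clones. Recovery with the block may therefore be understated. Splits of a group's samples were not tested because groups held 2 clones, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.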

Results

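Poly(A) RNA of the estrogen receptor-positive human breast cancer lines T-47D and MCF-7 was sequenced in clones whose ESR1, the gene of estrogen receptor alpha, was wild type (WT) or carried the Y537S or D538G substitution of the ligand-binding domain. Each line had 22 libraries in 11 groups of 2 clones. After 5 days in hormone-depleted medium, WT, Y537S and D538G clones received 0.1% DMSO or 10 nM estradiol for 8 h. WT clones were also kept in 10 nM estradiol for 5 to 25 days in steps of 5. No DMSO group was kept for those days, so time in culture was not separated from prolonged estradiol in either line. A time in hormone-depleted medium was recorded only for the 8 h groups, so depletion beforehand may differ as well. Total counts per library, in mega-counts, were 23.997 to 36.2 in the 8 h groups and 14.8 to 19.0 in the prolonged groups of T-47D, and 15.8 to 22.1 and 19.0 to 20.9 in those of MCF-7. Levels are CPM, counts scaled to the TMM-adjusted library size, given as mean ± SD of a group's 2 clones (10 libraries for all prolonged days together). Log2 changes are given ± a standard error derived from the test. It is the absolute log2 change divided by the square root of the F statistic, and so no separate measure of precision. Adjusted p-values are those of edgeR's quasi-likelihood test, with genes called below 0.05. Clones were the replicates, with 2 per genotype and line. Spread was pooled over the groups of a fit. Residual degrees of freedom were 6 at 8 h, 7 for prolonged estradiol and 8 for the trend. In the main fits, libraries of the same clone under different treatments or days were counted as independent. The p-values thus measure the spread of libraries around the fitted values, and not only the spread between clones. ESR1 itself stood at 93.7 ± 30.9 CPM in WT, 302 ± 214 in Y537S and 200.2 ± 27.0 in D538G T-47D clones under DMSO, with no call for Y537S (1.69 ± 0.54, adjusted p = 0.064) or D538G (1.09 ± 0.53, adjusted p = 0.173). The same groups of MCF-7 held 431 ± 221, 152 ± 58.3 and 408 ± 63.6 CPM of ESR1, again without a call. CDKN2A and MTAP, neighbours on chromosome 9 that MCF-7 is known to have lost, stood at 0 to 0.146 and 0.781 to 2.64 CPM over the MCF-7 libraries against 21.7 to 77.4 and 30.9 to 51.9 CPM in T-47D.

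**Figure D1:**
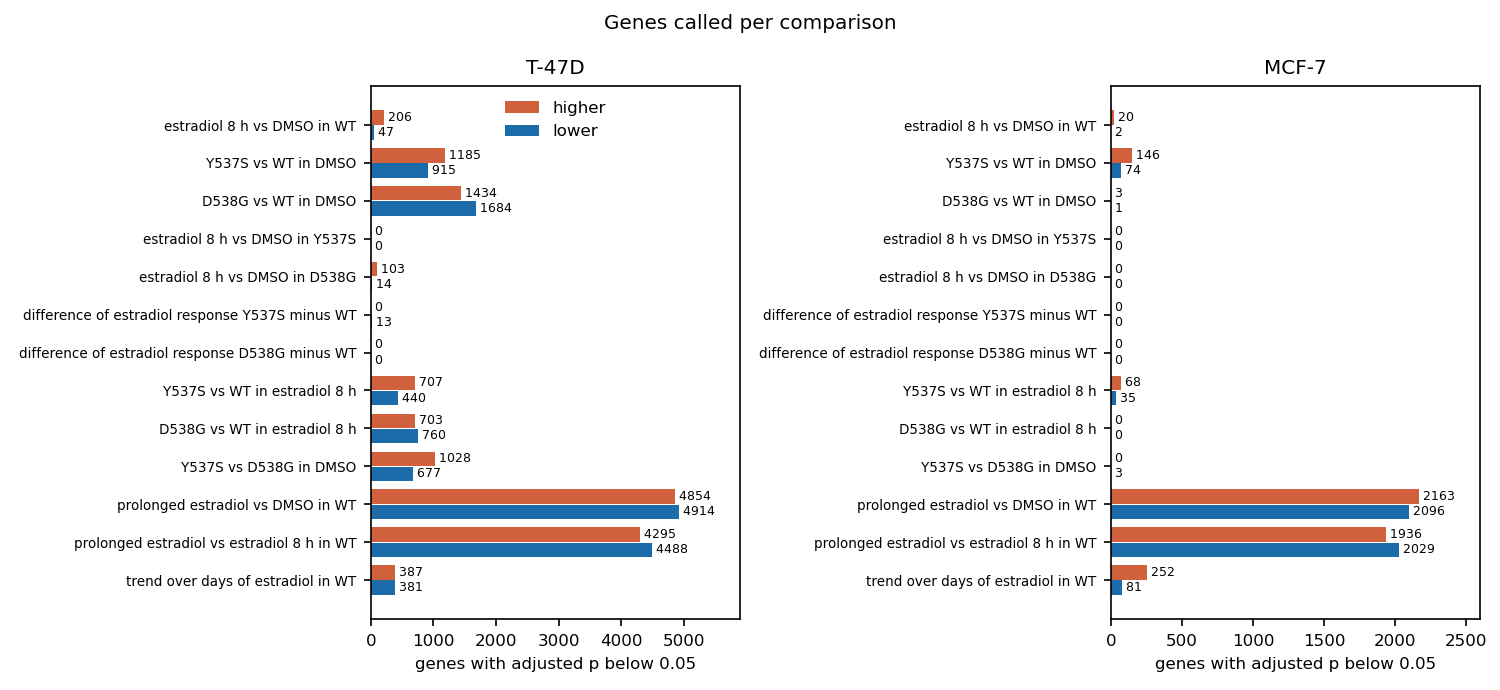
Number of genes with higher (orange) and lower (blue) expression at adjusted p below 0.05 in each comparison of T-47D and MCF-7 clones. For the trend, higher and lower mean a rising or falling level from day 5 to day 25.

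Estradiol for 8 h raised CXCL12, LINC01016 and GREB1 in WT T-47D clones. CXCL12, a chemokine ligand, was 50.2-fold higher (328 ± 31.1 against 6.65 ± 0.416 CPM, adjusted p = 0.000147), and the long noncoding RNA LINC01016 went from no counts to 10.9 ± 0.296 CPM, at least 184-fold higher (adjusted p = 2.07e-05). GREB1, an estrogen receptor cofactor, rose from 53.1 ± 4.45 to 429 ± 44.2 CPM (3.04 ± 0.17, adjusted p = 3.18e-05). Bounds of "at least" set 3 counts over the group against a group without counts, and ranges after a fold are 95% counting intervals for groups of 1 to 3 counts. Both cover counting error only. In all, 253 of 14972 genes were called, 206 higher and 47 lower. The largest increases took in the neuropeptide receptor NPY5R (at least 19.3-fold higher), the protease inhibitor SPINK4 (137-fold higher, 24.2 to 5455) and the transcription factor GATA4 (55.1-fold higher, 14.9 to 460.1). The potassium channel KCNK5 (46.8-fold), SUSD3 (31.2-fold), PLCL1 (26.8-fold), the adrenergic receptor ADRA2A (25.4-fold) and the exporter SLC47A1 (20.5-fold) also rose. The small GTPase ARL4A fell most, 3.99-fold (5.77 ± 0.0471 against 23.4 ± 1.89 CPM, adjusted p = 0.000408). Other decreases were in ITPRIP (-1.78), TSC22D3, a leucine zipper protein induced by glucocorticoid (-1.69), CHRM1 (-1.68), NDRG1 (-1.59), the mTORC1 inhibitor DDIT4 (-1.56), KCNC1 (-1.52), ANGPTL4 (-1.29), the sialyltransferase ST6GAL1 (-1.25) and DHRS3 (-1.25).

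Of 22 measured estrogen-induced targets in T-47D, 13 rose after 8 h and 9 were not called, 18 rising when adjusted over the list alone (list test adjusted p = 2.88e-49, and 0.00325 with an estimated correlation). GREB1, CXCL12, STC2 (3.59 ± 0.41) and the cyclin CCND1 (0.98 ± 0.13) had the smallest p. Of 10 estrogen-repressed targets 3 fell and 7 were not called (7 fell over the list alone, adjusted p = 9.21e-09 and 0.00697 with an estimated correlation): CCNG2 (-0.89), TGFB3 (-0.87) and TP53INP1 (-0.77). The ribosome biogenesis genes NOLC1 (0.63), POLR1B (0.80), NOP16 (0.79) and NOP56 (0.75) rose and 14 of that list were not called (11 over the list alone, adjusted p = 1e-09, and 0.0998 with an estimated correlation). The replication licensing factor CDC6 (0.95) was the only riser among 20 G1/S genes, 19 of which were not called (6 over the list alone, adjusted p = 4e-05, and 0.608 with an estimated correlation). The receptor partners RARA (1.11) and NRIP1 (0.91) rose while 15 of 17 were not called. In the growth factor list IGFBP4 (1.27), TGFA (0.82) and IGF1R (1.07) rose and 15 of 18 were not called. With the clone taken as a block, the count of called genes was 2668 (1195 higher and 1473 lower), against 677 by DESeq2 and 140 with only the compared groups in the fit. Leaving out WT DMSO clone 1 or 2 gave 50 and 68 calls, and leaving out WT estradiol clone 1 or 2 gave 139 and 57.

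Y537S T-47D clones, compared with WT under DMSO, carried the main estradiol-induced genes at raised levels without hormone, and had lower levels of the calprotectin subunits S100A8 and S100A9. CXCL12 was 36.2-fold higher (241 ± 78.4 against 6.65 ± 0.416 CPM, adjusted p = 0.000121) and GREB1 stood at 260.2 ± 5.07 against 53.1 ± 4.45 CPM (2.29 ± 0.16, adjusted p = 0.000119). S100A8 was 297-fold lower (1.17 ± 0.779 against 335 ± 382 CPM, adjusted p = 0.00697) and S100A9 26.6-fold lower (adjusted p = 0.00791). The test called 2100 genes, 1185 higher and 915 lower. Among the largest increases, LINC01016 was at least 28.0-fold higher, NPY5R at least 24.4-fold higher, SPINK4 374-fold higher (66.8 to 14790), the fatty acid elongase ELOVL2 238-fold higher (42.3 to 9409), FGFBP2 56.0-fold higher (9.75 to 2244) and GATA4 51.4-fold higher (13.9 to 429). The imprinted gene NDN (6.56), PXDNL (5.53) and the exchange factor RASGRF1 (5.26) also rose. The lectin CLEC3A was 752-fold lower (257 to 3649) and LINCR-0002 143-fold lower (48.5 to 697). Other decreases were those of LINC01519 (-7.03), the signalling ligand WNT5A (-6.61), DSCR8 (-6.26), the metalloproteinase MMP16 (-5.08) and FGD5 (-4.60). GAGE1 (-5.98) belongs to a family of near-identical genes, so which copy fell is uncertain.

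Estrogen-induced targets rose in 13 of 22 cases in Y537S T-47D clones and 9 were not called (17 over the list alone, adjusted p = 1.67e-15, and 0.0505 with an estimated correlation). TGFB3 (-1.18) and ERBB2 (-1.18) fell and 8 of 10 estrogen-repressed targets were not called (adjusted p = 0.00546, and 0.0856 with an estimated correlation). Mitotic genes rose in 16 of 20 cases and 4 were not called (20 over the list alone, adjusted p = 1.19e-16, and 0.197 with an estimated correlation). They took in the checkpoint kinase BUB1B (1.70), topoisomerase TOP2A (1.66) and the motor KIF11 (1.27). CDC6 (1.35), CCNE2 (1.01) and POLE2 (2.12-fold) were among the risers of the G1/S list. In all 11 of its 20 genes rose and 9 were not called (19 over the list alone, adjusted p = 8.31e-12, and 0.238 with an estimated correlation). Hypoxia and glycolysis genes fell in 12 of 17 cases, ADM (2.31) rose and 4 were not called (adjusted p = 1.64e-09, and 0.0855 with an estimated correlation). The luminal factors ELF3 (-1.31), AR (-0.77) and SPDEF (-0.64) and the cadherin CDH1 (-0.72) fell. With them 6 of 15 luminal genes fell and 9 were not called (adjusted p = 0.000694, and 0.0856 with an estimated correlation). Antiviral OAS3 (1.60), HERC6 (3.24) and OAS1 (1.93) rose and IFI6 (-0.72) fell among 19 interferon genes, with 15 not called (adjusted p = 0.00181, and 0.263 with an estimated correlation). The count of calls was 781 or 823 without WT DMSO clone 1 or 2, 1314 without Y537S DMSO clone 1, and 209 with only the compared groups in the fit.

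D538G T-47D clones under DMSO had raised GREB1 and CXCL12, each by less than in Y537S clones, and many other changes. GREB1 was at 97.4 ± 5.77 against 53.1 ± 4.45 CPM (0.87 ± 0.16, adjusted p = 0.00521) and CXCL12 at 41.2 ± 16.5 against 6.65 ± 0.416 CPM (2.63 ± 0.34, adjusted p = 0.00145). The receptor subunit GFRA1 was 257-fold higher (36.5 ± 13.5 against 0.137 ± 0.0112 CPM, adjusted p = 0.0119) and the collagen hydroxylase P3H2 rose too (5.40 ± 0.36, adjusted p = 0.000257). Calls covered 3118 genes, 1434 higher and 1684 lower. ELOVL2 was 402-fold higher (71.8 to 15910), FGFBP2 40.4-fold higher (6.89 to 1629), NPY5R at least 12.3-fold higher and LINC01016 at least 4.10-fold higher. NDN (6.88), COX7B2 (6.45), the creatine synthesis enzyme GATM (5.25) and the kinase inhibitor PKIA (5.12) rose. NUPR1L was at least 70.6-fold lower, SPINK13 382-fold lower (105 to 3163) and DSCR8 321-fold lower (109 to 1559). CLEC3A (-8.01), LINC00836 (-7.78), WNT5A (-5.84), ZMAT4 (-5.38), the sulfatase ARSJ (-5.35), LINC01519 (-5.26) and S100A8 (-5.15) fell.

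Only 6 of 22 estrogen-induced targets rose in D538G T-47D clones and 16 were not called (6 over the list alone, adjusted p = 0.0276, and 0.738 with an estimated correlation). CA12 (1.08), MYB (1.48), CXCL12 and GREB1 had the smallest p. Mitotic genes rose in 9 of 20 cases and 11 were not called (11 over the list alone, adjusted p = 9.59e-07, and 0.738 with an estimated correlation), including KIF11 (2.29-fold) and BUB1B (2.82-fold). G1/S genes gave 6 increases and the fall of GINS2 (-0.97), with 13 not called (adjusted p = 0.0403, and 0.907 with an estimated correlation). The mesenchymal genes S100A4 (-3.00), VIM (-3.66) and FN1 (-0.98) fell and 7 of 10 were not called, and the receptor kinase IGF1R (1.70) rose. Leaving out WT DMSO clone 1 or 2 gave 1053 and 1644 calls, and leaving out D538G DMSO clone 1 or 2 gave 1245 and 1359.

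Direct comparison of the mutants under DMSO placed GREB1 (1.42 ± 0.16, adjusted p = 0.0018) and CXCL12 (2.55 ± 0.33, adjusted p = 0.00257) higher in Y537S than in D538G T-47D clones. The zinc finger gene ZNF655 was 60.5-fold higher (63.8 ± 4.94 against 1.06 ± 0.323 CPM, adjusted p = 1.96e-06) and P3H2 97.3-fold lower in Y537S (adjusted p = 6.99e-05). Of 1705 called genes 1028 were higher in Y537S and 677 lower. NUPR1L was at least 38.7-fold higher, GATA4 117-fold higher (20.6 to 4660), SPINK13 58.1-fold higher (15.8 to 485) and SPINK4 52.4-fold higher. LINCR-0002 was 285-fold lower (97.1 to 1384) and PKIA (-5.96) and TRIM58 (-4.81) were lower. PGAM4 (-5.48), an intronless copy that can share reads with PGAM1, is uncertain. Estrogen-induced targets were higher in Y537S in 8 of 22 cases, lower in 1 and not called in 13 (adjusted p = 3.93e-08, and 0.21 with an estimated correlation). In the interferon list 8 of 19 genes were higher and 11 not called (adjusted p = 0.000526, and 0.365 with an estimated correlation). Without D538G DMSO clone 1 or 2 the count was 227 and 556, and with only the compared groups in the fit it was 14.

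Genes changed by estradiol in WT T-47D clones and by a mutation under DMSO included GREB1, CXCL12 and NPY5R for both mutations. Estradiol and Y537S shared 166 genes in the same direction (137 higher, 29 lower), against 19.2 from list sizes alone and 0 in simulated unchanged groups with the same shared DMSO libraries. Those simulations called 0.2 and 0.15 genes on average, so their count of 0 does not measure what shared libraries add at the observed list sizes. For D538G the shared genes were 112 (90 higher, 22 lower) against 25.0, and the mutations shared 1025 (605 higher, 420 lower) against 216, with 22 called in opposite directions. With the clone as a block in the estradiol comparison the balance moved, to 753 shared with Y537S (402 higher, 351 lower) against 185 and 980 with D538G (342 higher, 638 lower) against 280. The covariance of the log2 changes was 0.261 for estradiol and Y537S, 0.176 for estradiol and D538G and 0.459 for the mutations. Simulated values were 0.0864, 0.0873 and 0.0870. The correlations were 0.506, 0.332 and 0.591 against simulated values of 0.506, 0.508 and 0.511. Those of the estradiol pairs were no higher than the simulated values. The simulated groups held noise alone, for which a shared reference sets a correlation of about this size. It therefore gives no benchmark for groups with real changes. Without a shared library, r was 0.301 for estradiol in D538G with Y537S under DMSO. For estradiol in Y537S with D538G under DMSO it was 0.0712. Part of each excess in shared genes and covariance may come from the WT DMSO libraries used on both sides. That share cannot be separated with 2 clones. Shifted neighbourhoods common to both mutants may also add to the genes they share. On chromosome 15 these held 350 of 497 genes in Y537S and 420 in D538G. Their median log2 shifts from the same WT clones were 0.567 and 0.565. Between Y537S under DMSO and estradiol in D538G clones, which share no library, 83 genes moved alike (71 higher, 12 lower) against 9.01 from list sizes. Estradiol in Y537S clones, whose comparison shares no library with D538G under DMSO either, called 0 genes, so only the blocked fit can be compared. It gave 20 shared genes against 8.57 there and 338 against 62.6 for the first pair. Of the 2100 genes called for Y537S, 753 moved the same way after 8 h of estradiol in WT clones with the clone as a block, a further 995 only after prolonged estradiol, and 352 in neither. For D538G these numbers were 980, 1291 and 847. Prolonged estradiol called most genes and used the same DMSO libraries, and its whole overlap was 1709 genes for Y537S against 699 from list sizes and 2205 for D538G against 1036.

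**Figure D2:**
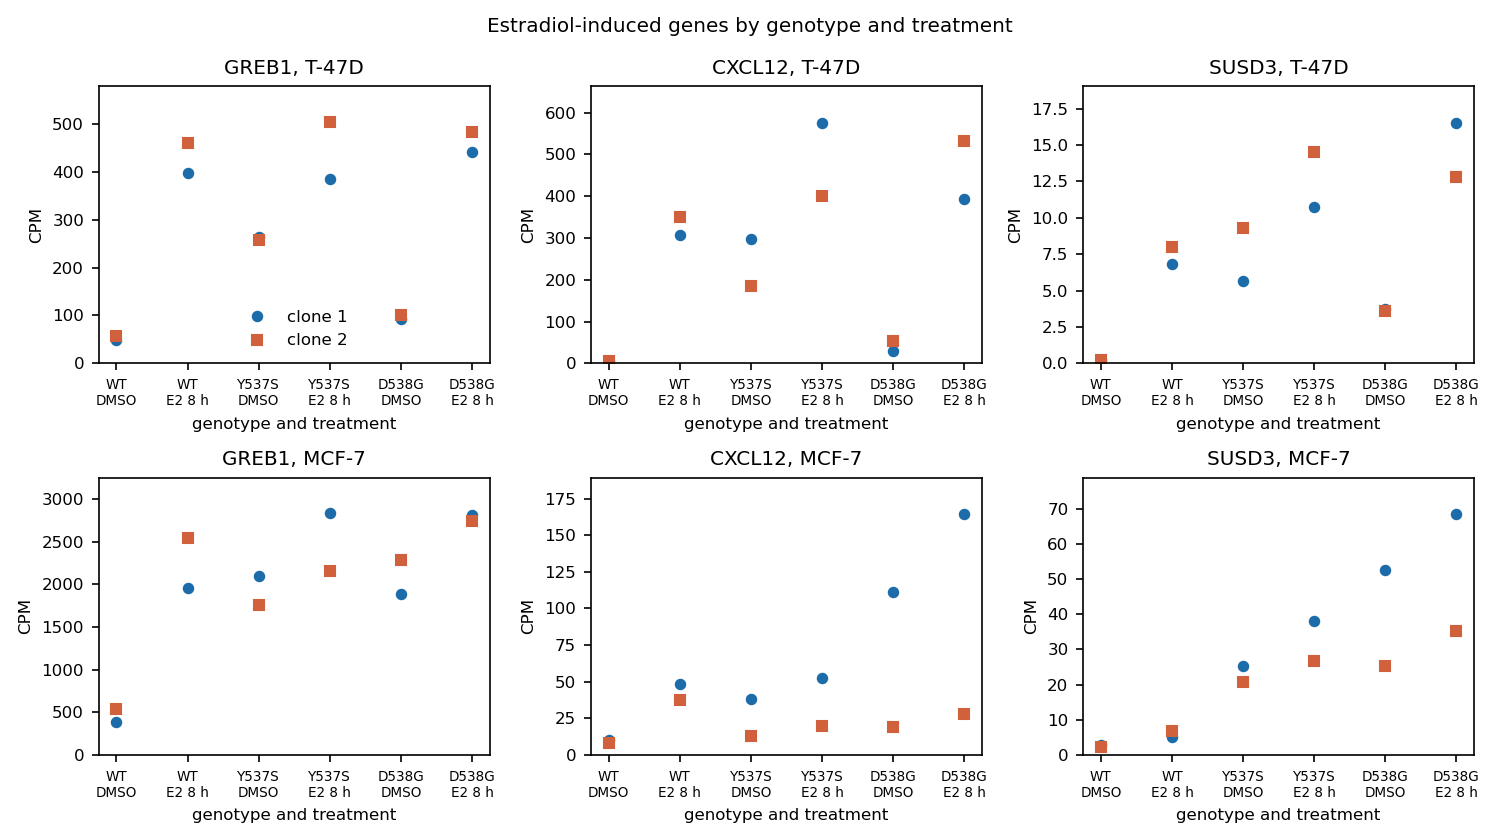
Expression of GREB1, CXCL12 and SUSD3 in CPM in each library of WT, Y537S and D538G clones under DMSO or 10 nM estradiol (E2) for 8 h. Each point is 1 library and the symbol gives the clone number within its genotype.

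Estradiol still raised GREB1 in D538G T-47D clones, from 97.4 ± 5.77 to 462 ± 29.3 CPM (2.28 ± 0.16, adjusted p = 0.00036). In Y537S clones the level went from 260.2 ± 5.07 to 444 ± 84.2 CPM without a call (0.77 ± 0.15, adjusted p = 0.789). In D538G clones 117 genes were called, 103 higher and 14 lower. LINC01016 rose there 72.9-fold (17.5 ± 0.763 against 0.242 ± 0.00110 CPM, adjusted p = 7.73e-05), and GATA4 was 125-fold higher (21.97 to 4981). PLCL1 (4.05), SPINK4 (4.02) and NXPH3 (16.0-fold) rose as well. Decreases were those of ARL4A (-1.42), FSIP2 (-1.28), RND1 (-1.10), TSC22D3 (-0.98) and CCNG2 (-0.96). Estrogen-induced targets rose in 10 of 22 cases in D538G and 12 were not called (16 over the list alone, adjusted p = 2.58e-65 and 0.000964 with an estimated correlation). With the clone as a block 868 genes were called in D538G, and leaving out D538G DMSO clone 1 or 2 or D538G estradiol clone 1 or 2 gave 9, 22, 31 and 23. In Y537S clones edgeR called 0 genes (325 at unadjusted p below 0.05), DESeq2 called 19 and edgeR with the clone as a block 86, and 1 was called without Y537S DMSO clone 1. Its 22 estrogen-induced targets had a median log2 change of 0.60 with none called, 11 over the list alone (adjusted p = 1.29e-35 and 0.00372 with an estimated correlation), STC2 (1.13 ± 0.37) and CCND1 (0.58 ± 0.13) among them.

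The weaker response of Y537S T-47D clones was tested as a difference from the WT response, and CXCL12 (difference -4.64 ± 0.47, adjusted p = 0.00565) and SUSD3 (-4.21 ± 0.46, adjusted p = 0.00592) responded less. The 13 genes called all responded less in Y537S, with LINC01016 (-9.03), SPINK4 (-6.47) and the cytochrome CYP2S1 (-2.94) among them; LINC01016 and SPINK4 rest on WT DMSO groups of at most 3 counts. GREB1 responded less by the same measure (-2.27 ± 0.22, adjusted p = 0.00565), and 2 of 22 estrogen-induced targets were called with 20 not called (7 over the list alone, adjusted p = 6.86e-27 and 0.0131 with an estimated correlation). With the clone as a block 128 genes were called, 118 of them lower, and the count was 7 without WT DMSO clone 1 and 4 without Y537S estradiol clone 1. No gene was called for D538G minus WT by edgeR (272 at unadjusted p below 0.05), against 7 by DESeq2 and 5 with the clone as a block, GREB1 standing at -0.76 ± 0.22 and CXCL12 at -2.13 ± 0.45.

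Genotype comparisons within estradiol-treated T-47D clones also called NDN, higher by 7.94 in Y537S (adjusted p = 0.0101) and 8.06 in D538G (adjusted p = 0.00875). In Y537S 1147 genes were called, 707 higher and 440 lower. ELOVL2 (6.03), the choline transporter-like SLC44A5 (6.01), RASGRF1 (5.85) and GATM (5.30) were higher and LINCR-0002 (at least 140.1-fold lower), S100A8 (-8.12), CLEC3A (-7.96), DSCR8 (-6.94) and LINC01519 (-6.64) lower. Mitotic genes were higher in 16 of 20 cases and not called in 4 (adjusted p = 1.88e-24, and 0.126 with an estimated correlation), including TOP2A (1.60) and BUB1B (1.49). In D538G 1463 genes were called, 703 higher and 760 lower. COX7B2 (156-fold higher, 52.9 to 757), ELOVL2 (7.93), GFRA1 (6.65) and P3H2 (5.89) were higher and NUPR1L (at least 35.2-fold lower), DSCR8 (505-fold lower, 90.2 to 19970), CLEC3A (-7.91), SPINK13 (-7.62) and LINC00836 (-7.55) lower. Without WT estradiol clone 1 or 2 the Y537S count was 325 and 382, and without Y537S estradiol clone 1 or 2 it was 477 and 639. The D538G count was 341 and 556 without WT estradiol clone 1 or 2 and 328 and 215 without D538G estradiol clone 1 or 2.

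Prolonged estradiol, taken over 5 to 25 days, kept GREB1 induced in WT T-47D clones at 481 ± 42.9 against 53.1 ± 4.45 CPM (3.19 ± 0.09, adjusted p = 4.85e-11). ESR1 stood at 127 ± 14.8 CPM (0.45 ± 0.14, adjusted p = 0.0132). S100A8 fell 374-fold (1.16 ± 0.857 against 335 ± 382 CPM, adjusted p = 5.33e-07), and the cadherin CDH10 also fell (-7.68 ± 0.20, adjusted p = 4.33e-11). Of 14417 genes 9768 were called against DMSO, 4854 higher and 4914 lower, and single days gave 8452, 8751, 8558, 8710 and 8692 calls from day 5 to day 25. Spread was pooled over all WT groups, and clones differed less at the days than under DMSO. The spread of the DMSO group may thus be understated in these counts. Thyrotropin-releasing hormone TRH was at least 111-fold higher, LINC01016 at least 128-fold higher, GGT5 at least 44.8-fold higher and CD22 at least 25.4-fold higher. SPRY4 was at least 23.02-fold higher, NPY5R at least 21.4-fold higher, GATA4 404-fold higher (112 to 3335) and FGFBP2 374-fold higher (67.0 to 14780). CLEC3A (-9.47), LINC01519 (-9.18), the formyl peptide receptor FPR3 (-8.72), MCF2 (-8.41), DEFB132 (-8.11) and LOC100132735 (-6.88) fell. NBPF13P (-6.53) and ZNF350-AS1 (-6.77) share sequence or position with other genes and are uncertain. RPS18 (435-fold higher, 78.0 to 17210) and BAG6 (at least 31.1-fold higher) lie in a chromosome 6 neighbourhood with few counts in any library, so their increases are uncertain. All 24 measured estrogen-induced targets rose (adjusted p = 5.55e-16 and 0.046 with an estimated correlation), and 9 of 10 estrogen-repressed targets fell and 1 rose (adjusted p = 1.76e-05 and 0.0494). Mitotic genes rose in 19 of 20 cases with 1 not called (adjusted p = 3.78e-09, and 0.503 with an estimated correlation), TOP2A (2.06) among them. Of 19 interferon genes 13 rose, 2 fell and 4 were not called (adjusted p = 0.00204, and 0.336 with an estimated correlation).

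Against estradiol for 8 h, prolonged treatment of T-47D clones raised OAS1 (2.63 ± 0.25, adjusted p = 2.16e-06) and TOP2A (1.89 ± 0.11, adjusted p = 6.76e-08) and lowered S100A8 (-7.78 ± 0.75, adjusted p = 2.78e-06). The test called 8783 genes, 4295 higher and 4488 lower. Increases took in INHBE (146-fold higher, 49.9 to 709), TNFRSF18 (73.1-fold higher, 20.1 to 605) and the mucin MUC5B (84.5-fold higher, 15.1 to 3350), and decreases MCF2 (-8.98), CLEC3A (-8.62), LINC01519 (-8.36) and FPR3 (-8.06). All 20 mitotic genes rose (adjusted p = 3.6e-13, and 0.366 with an estimated correlation), as did 15 of 19 interferon genes with 4 not called (adjusted p = 3.17e-06, and 0.212 with an estimated correlation). Ribosome biogenesis genes fell in 12 of 18 cases, rose in 1 and were not called in 5 (adjusted p = 0.0309, and 0.478 with an estimated correlation). Cholesterol genes fell in 11 of 18 cases and 7 were not called (adjusted p = 0.0309, and 0.509 with an estimated correlation).

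Within the prolonged T-47D groups, the interferon-stimulated gene IFI27 climbed from day 5 to day 25 and the gap junction gene GJA1 declined. IFI27 rose from 0.597 ± 0.181 to 12.9 ± 2.76 CPM (log2 change per day 0.19 ± 0.03, adjusted p = 0.00979) and GJA1 fell from 39.0 ± 25.4 to 1.00 ± 1.02 CPM (-0.25 ± 0.03, adjusted p = 0.0026). Of 14083 genes 768 had a slope, 387 rising and 381 falling. The channel regulator CLCA2 (0.21), GDF15 (0.19), LAMP3 (0.18) and S100A8 (0.15) rose, and the protease inhibitor SPINK5 (-0.24), DPYSL3 (-0.18), LINCR-0002 (-0.18) and MMP16 (-0.17) fell. Interferon genes rose in 10 of 19 cases and 9 were not called (15 over the list alone, adjusted p = 8.23e-17, and 0.0566 with an estimated correlation), led by OAS2 (0.14), IFI6 (0.13), OAS1 (0.12) and MX1 (0.10). G1/S genes fell in 2 of 20 cases and 18 were not called (18 over the list alone, adjusted p = 4.96e-10, and 0.327 with an estimated correlation). The count of slopes was 90, 446, 237 and 3312 without the day 5, 15, 20 and 25 libraries of clone 1, and 75, 1744, 309, 238 and 477 without the day 5, 10, 15, 20 and 25 libraries of clone 2.

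**Figure D3:**
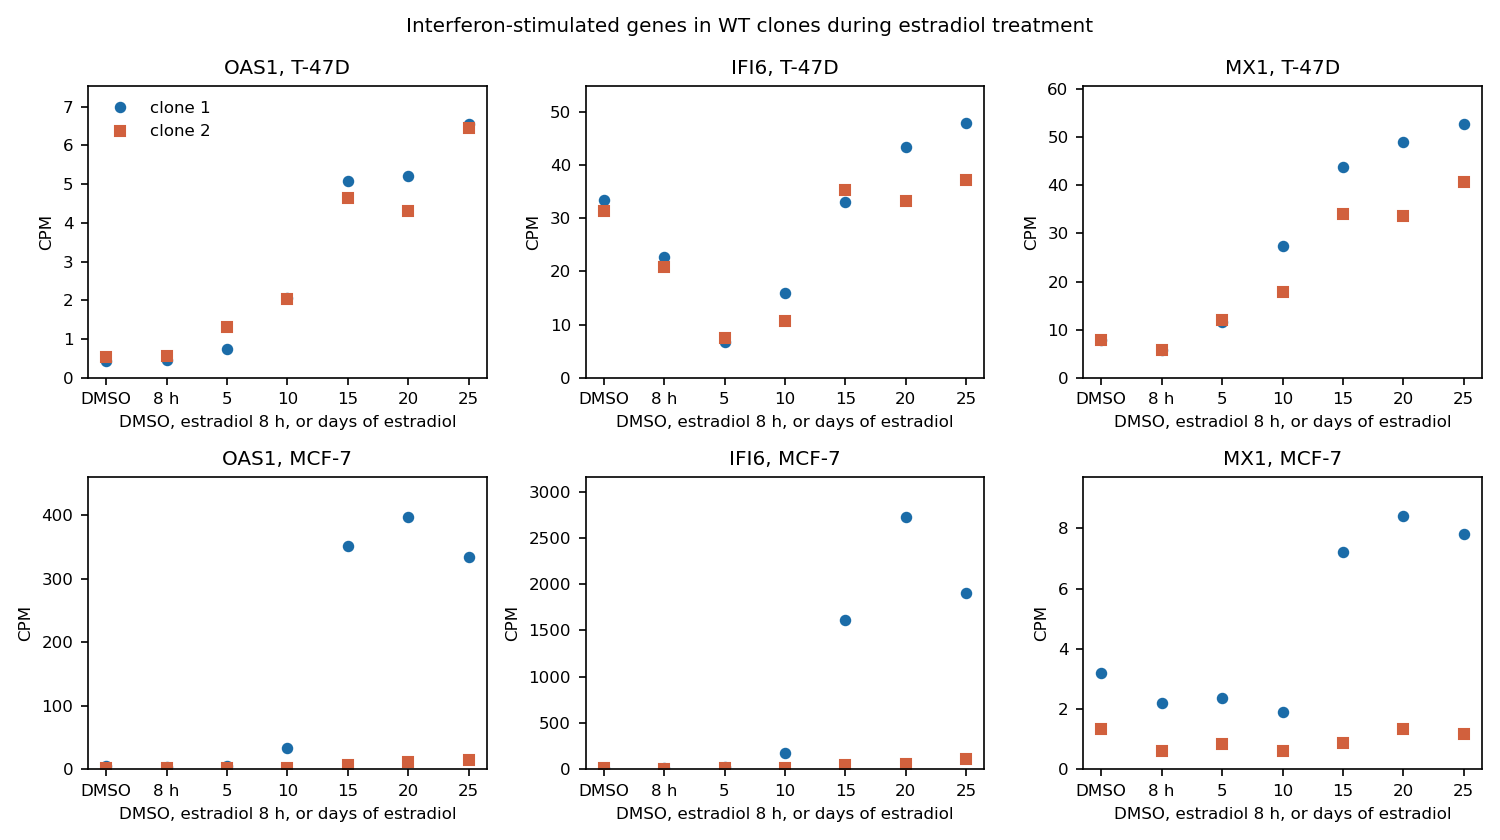
Expression of the interferon-stimulated genes OAS1, IFI6 and MX1 in CPM in WT clones under DMSO, estradiol for 8 h and estradiol for 5 to 25 days. Each point is 1 library and the symbol gives the clone number.

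Estradiol for 8 h raised GREB1 in WT MCF-7 clones from 465 ± 111 to 2250 ± 412 CPM (2.26 ± 0.23, adjusted p = 0.0139). The immediate early transcription factor EGR3 rose 7.76-fold (87.9 ± 33.5 against 11.2 ± 0.415 CPM, adjusted p = 0.016). CYP1A1, a hydrocarbon-metabolising cytochrome, fell 5.75-fold (1.36 ± 0.370 against 7.75 ± 0.787 CPM, adjusted p = 0.0196), and so did the p53 target TP53INP1 (-1.44 ± 0.18, adjusted p = 0.0232). Only 22 of 14699 genes were called, 20 higher and 2 lower. Transglutaminase TGM2 was 17.9-fold, OTOF 16.5-fold, tyrosine hydroxylase TH 14.9-fold, SEC14L2 6.23-fold, RAPGEFL1 6.13-fold, the RNA-binding RBM24 5.82-fold, the antitrypsin gene SERPINA1 5.63-fold and ADAMTSL5 4.69-fold higher. GREB1 and EGR3 were the 2 of 23 estrogen-induced targets that rose, 21 being not called (16 over the list alone, adjusted p = 1.36e-37 and 0.0187 with an estimated correlation), with a median log2 change of 1.27 over the list. CYP1A1 and TP53INP1 were the estrogen-repressed targets that fell, 10 of 12 being not called (8 over the list alone, adjusted p = 2.08e-13 and 0.0215 with an estimated correlation). None of 20 G1/S genes was called (5 over the list alone, adjusted p = 7.71e-12 and 0.0283 with an estimated correlation), nor any of 18 ribosome biogenesis genes (10 over the list alone, adjusted p = 1.19e-12, and 0.0559 with an estimated correlation). With the clone as a block 2084 genes were called, 1081 higher and 1003 lower, against 340 by DESeq2 and 0 with only the compared groups in the fit. Without WT DMSO clone 1 or 2 the count was 1 in both cases, and without WT estradiol clone 1 or 2 it was 40 and 0.

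Y537S MCF-7 clones under DMSO had raised GREB1 (1931 ± 237 against 465 ± 111 CPM, 2.04 ± 0.23, adjusted p = 0.0104) and raised SERPINA3, an acute-phase protease inhibitor, 58.4-fold (68.4 ± 58.8 against 1.16 ± 0.546 CPM, adjusted p = 0.034). ID2, an inhibitor of helix-loop-helix transcription factors, fell 9.28-fold (10.9 ± 2.55 against 101 ± 8.05 CPM, adjusted p = 0.00825). The test called 220 genes, 146 higher and 74 lower. The epidermal protease CASP14 was 659.7-fold higher (118 to 26090), GUCY1A2 182-fold higher (61.9 to 883), the TGF-beta receptor TGFBR2 138-fold higher (47.1 to 673), PHLDB2 46.4-fold higher (15.6 to 227) and the cytokine IL20 41.1-fold higher (11.1 to 344). The integrin ITGB6 (5.35), NUPR1 (5.75), NAV2 (5.49) and PPP1R1C (4.41) rose. The chromosome 19 zinc finger genes ZNF347 (at least 92.7-fold lower), ZNF264 (126-fold lower, 34.4 to 1046) and ZNF880 (-6.03) fell most, with LOC101928233 (-5.89), GRHL3 (-4.86), the interleukin receptor IL1R1 (-3.98) and RAI2 (-3.13). HLA-DRB1 (-3.76) and HLA-DRB5 (-3.40) also fell, paralogs that share reads and are uncertain. Neighbourhoods shifted in both Y537S clones held 73 of 1063 genes on chromosome 19 (median log2 shift -0.648). On chromosome 22 they held 178 of 378 (0.516). Inside such neighbourhoods 9.56% of genes were called, against 1.36% outside. With each gene centred on its neighbours, 20.8% and 82.1% of these calls remained. No DNA was measured, so copy-number differences between clones cannot be told apart from effects of Y537S. GREB1, FHL2 (2.96), MYC (1.24) and EGR3 (1.66) were the 4 of 23 estrogen-induced targets that rose, 19 being not called (15 over the list alone, adjusted p = 1.25e-16, and 0.109 with an estimated correlation). IFI27 (3.39) was the only 1 of 18 interferon genes to rise, 17 being not called (9 over the list alone, adjusted p = 7.87e-11, and 0.296 with an estimated correlation). The laminin genes LAMA3 (1.48) and LAMC2 (2.46) rose among 14 basal genes with 12 not called (adjusted p = 0.000194, and 0.133 with an estimated correlation). Without WT DMSO clone 1 or 2 the calls were 5 and 4, and without Y537S DMSO clone 1 or 2 they were 63 and 4. DESeq2 called 1031, the fit without the low-count filter 407 and that of only the compared groups 19.

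D538G MCF-7 clones differed from WT under DMSO in 4 genes called by edgeR, against 497 by DESeq2, 87 without the low-count filter and 33 with the clone number as a block. GREB1 (2087 ± 285 against 465 ± 111 CPM, 2.16 ± 0.23, adjusted p = 0.0377), SUSD3 (15.4-fold, adjusted p = 0.0429) and SERPINA1 (8.50-fold, adjusted p = 0.0377) were higher, and ID2 fell 7.07-fold (adjusted p = 0.0377). GREB1 was the only called gene of 23 estrogen-induced targets, 22 being not called (15 over the list alone, adjusted p = 4.27e-25 and 0.0408 with an estimated correlation). The list's median log2 change was 1.45, as it was in Y537S. The count was 0 and 1 without WT DMSO clone 1 or 2 and 0 without either D538G DMSO clone. ZNF347 (at least 83.1-fold lower), ZNF264 (223-fold lower, 61.2 to 1845) and ZNF880 (-5.92) were the 3 genes called between the mutants, all lower in Y537S, against 91 by DESeq2. All 3 remained called with each gene centred on its neighbours, but their copy number was not measured. Estradiol and Y537S shared 9 genes in the same direction, GREB1 and EGR3 among them, against 0.209 from list sizes, estradiol and D538G shared 2, and the mutations shared 4. The covariance of the log2 changes was 0.221, 0.195 and 0.475 for these pairs against 0.105, 0.106 and 0.107 in simulated unchanged groups. Part of the covariance may come from the shared DMSO libraries. The correlations were 0.420, 0.439 and 0.708 against simulated values of 0.510, 0.510 and 0.516. Those of the estradiol pairs were no higher than the simulated values, which a shared reference sets for noise alone. They therefore give no benchmark for groups with real changes. Without a shared library, r was 0.234 for estradiol in D538G with Y537S under DMSO. For estradiol in Y537S with D538G under DMSO it was 0.122.

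GREB1 stood higher under estradiol than under DMSO in each of the 4 mutant MCF-7 clones without a call, at 2496 ± 481 against 1931 ± 237 CPM in Y537S (0.37 ± 0.22, adjusted p = 1, 0.944 with the clone as a block). In D538G it was 2778 ± 55.6 against 2087 ± 285 CPM (0.42 ± 0.22, adjusted p = 1, 0.347 with the clone as a block). In Y537S edgeR called 0 genes (76 at unadjusted p below 0.05), as did DESeq2 and the fit with the clone as a block, and leaving out Y537S DMSO clone 1 gave 1. In D538G edgeR called 0 (116 at unadjusted p below 0.05), DESeq2 called 2 and the blocked fit 0, and leaving out D538G estradiol clone 2 gave 2. The 23 estrogen-induced targets had median log2 changes of 0.32 in Y537S (adjusted p = 1.68e-10, and 0.198 with an estimated correlation) and 0.48 in D538G (adjusted p = 3.39e-19 and 0.0441 with an estimated correlation), none being called in either. Tested as a difference from the WT response, GREB1 gave -1.89 ± 0.32, adjusted p = 0.698 in Y537S and -1.84 ± 0.32, adjusted p = 1 in D538G, and blocked adjusted p-values of 0.00291 and 0.00628. The difference had 0 calls in Y537S by edgeR (402 at unadjusted p below 0.05), 15 by DESeq2 and 208 with the clone as a block. In D538G it had 0 by edgeR (284 at unadjusted p below 0.05), 4 by DESeq2 and 51 with the block. The estrogen-induced targets leaned lower in Y537S minus WT (median log2 difference -0.96, adjusted p = 3e-28 and 0.023 with an estimated correlation), 14 of them being called lower with the block. In D538G minus WT 9 were called lower with the block (median -0.83, adjusted p = 7.99e-25 and 0.0475 with an estimated correlation).

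Within estradiol-treated MCF-7 clones, CASP14 was at least 229-fold higher in Y537S than in WT (adjusted p = 0.0259) and ITGB6 57.8-fold higher (108 ± 73.5 against 1.86 ± 0.941 CPM, adjusted p = 0.029). Of 103 called genes 68 were higher and 35 lower, with PHLDB2 (87.6-fold higher, 23.9 to 730.2), TGFBR2 (4.12) and IFI27 (3.85) higher and ZNF347 (102-fold lower, 27.8 to 845), ZNF264 (60.2-fold lower, 20.3 to 294), ZNF880 (-5.74) and OTOF (-2.86) lower. The count was 3 and 4 without WT estradiol clone 1 or 2 and 19 and 0 without Y537S estradiol clone 1 or 2, against 675 by DESeq2 and 8 with only the compared groups in the fit. For D538G edgeR called 0 genes (2104 at unadjusted p below 0.05), DESeq2 called 471, and 2 were called without D538G estradiol clone 2, while GREB1 stood at 0.31 ± 0.22 and SUSD3 at 3.13 ± 0.44.

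Prolonged estradiol raised GREB1 in WT MCF-7 clones to 3542 ± 646 CPM (2.90 ± 0.22, adjusted p = 0.000143) and SERPINA3 91.0-fold (121 ± 63.0 against 1.16 ± 0.546 CPM, adjusted p = 0.000251). It lowered ESR1 to 126 ± 31.9 CPM (-1.82 ± 0.25, adjusted p = 0.00106) and the epithelial factor GRHL3 26.0-fold (2.96 ± 2.70 against 59.7 ± 35.7 CPM, adjusted p = 0.000545). Time in culture may add to these changes, as no DMSO group was kept so long. Of 14741 genes 4259 were called against DMSO, 2163 higher and 2096 lower, and single days gave 2121, 1309, 1508, 3421 and 3469 calls from day 5 to day 25. The neurotrophic receptor GFRA2 was at least 70.8-fold higher, B3GNT6 at least 15.4-fold higher, the nitric oxide synthase NOS3 199.6-fold higher (55.2 to 1650) and IL20 162-fold higher (44.6 to 1334). CASP14 was 153-fold higher (27.4 to 6061), S100A7 140.4-fold higher (38.8 to 1160) and IL24 90.1-fold higher (16.1 to 3566), while GATA4 (6.34) and the kallikrein KLK11 (6.06) rose. LOC101928233 (-4.53), MIR503HG (-3.99), IL1R1 (-3.88), the retinoic acid hydroxylase CYP26B1 (-3.82), LINC01106 (-3.74) and the calcium binder PVALB (-3.73) fell. MIR6723 (-7.12), NPHP3-ACAD11 (-3.66) and RBM5-AS1 (-3.40) overlap or resemble other genes and are uncertain. Estrogen-induced targets rose in 19 of 23 cases and 4 were not called (adjusted p = 1.01e-19 and 0.0472 with an estimated correlation). Immediate early genes rose in 14 of 17 cases and 3 were not called (adjusted p = 1.82e-13, and 0.108 with an estimated correlation), FOS (3.57) and EGR1 (2.86) among them. None of 21 interferon genes was called at a median log2 change of 3.17, 14 being called with the clone as a block (adjusted p = 0.033, and 0.672 with an estimated correlation), such as OAS1 (4.09 ± 2.03, blocked adjusted p = 0.014). Clone 1 stood apart, with OAS1 at 335 CPM on day 25 against 14.3 CPM in clone 2. With GC content and length corrected together 2709 genes were called, 49.6% of the original calls among them, and leaving out WT DMSO clone 1 or 2 gave 903 and 1980.

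Against estradiol for 8 h, prolonged treatment of MCF-7 clones changed 3965 genes, 1936 higher and 2029 lower. It raised CASP14 (at least 57.5-fold higher), S100A7 (316-fold higher, 56.7 to 12500), SLC6A20 (at least 22.6-fold higher), the keratin KRT5 (150-fold higher, 26.8 to 5934) and NOS3 (5.94 ± 0.53, adjusted p = 0.000362). MIR503HG (-4.30), CYP26B1 (-3.96), the nuclear receptor NR5A2 (-3.72 ± 0.38, adjusted p = 0.000583), PVALB (-3.68) and GALNT5 (-3.57) fell. G1/S genes fell in 11 of 20 cases, rose in 1 and were not called in 8 (adjusted p = 6.36e-07, and 0.146 with an estimated correlation), CDC6 standing at -0.87 ± 0.11. With GC content and length corrected the count was 2059, 40.4% of the original calls among them, and without WT estradiol clone 1 or 2 it was 1388 and 1051.

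From day 5 to day 25 the MCF-7 clones gained CYP1A1 (0.493 ± 0.407 to 11.6 ± 2.77 CPM, log2 change per day 0.28 ± 0.05, adjusted p = 0.0203). BCAS1 rose too (5.69 ± 3.55 to 107 ± 47.3 CPM, 0.24 ± 0.03, adjusted p = 0.00546), and the protocadherin PCDH10 fell (54.0 ± 25.0 to 5.18 ± 0.881 CPM, -0.19 ± 0.02, adjusted p = 0.00411). Of 14405 genes 333 had a slope, 252 rising and 81 falling. ZNF26 (0.29), MAPK4 (0.24) and the deiodinase DIO1 (0.23) rose, and PLIN5 (-0.19), KLHL4 (-0.14), PGLYRP2 (-0.14) and KIF12 (-0.11) fell. The estrogen-induced targets PGR (-0.11) and EGR3 (-0.07) fell with 21 of 23 not called, and the repressed targets PSCA (0.14) and CYP1A1 rose with 10 of 12 not called. With the clone as a block 1121 genes had a slope. Without the day 5, 10, 15 and 20 libraries of clone 1 the count was 95, 121, 218 and 206, and without the day 10, 15, 20 and 25 libraries of clone 2 it was 114, 161, 176 and 543.

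Across the lines, Y537S raised SUSD3 (4.95 in T-47D, 3.19 in MCF-7), IFITM10 (2.87, 2.81), GREB1 (2.29, 2.04) and RAPGEFL1 (2.70, 1.82). Also higher in both were the protein C receptor PROCR (1.64, 1.81), CT62 (1.62, 2.21), C5AR2 (2.11, 1.59) and FSIP1 (1.49, 2.75), and lower LOC101928233 (-3.55, -5.89) and clusterin CLU (-1.71, -1.81). In all, 31 genes were called the same way for Y537S in both lines (22 higher, 9 lower) against 15.0 from list sizes (exact hypergeometric test, p = 0.000933 for higher and 0.0242 for lower). Opposite directions were called for 19 against 13.6 from list sizes, and the log2 changes of all genes correlated with r = 0.0441. D538G gave 2 such genes against 0.415, and estradiol for 8 h gave 11 (10 higher, 1 lower) against 0.232, or 589 (378 higher, 211 lower) against 180 with the clone as a block. GREB1 was called for estradiol, Y537S and D538G in both lines, while CXCL12, 5.18 in Y537S T-47D clones, stood at 1.45 ± 0.99 in MCF-7 (adjusted p = 0.502). Fitted together, the lines differed in the Y537S effect for 1021 genes (428 higher and 593 lower in MCF-7), among them FLT4, and in the D538G effect for 1009 (528 higher, 481 lower). Their estradiol response differed for 4 genes, or 835 with the clone as a block.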

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

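The tests of clone differences between 8 h and days, of growth of the response from day 5 to 25, of a WT-sized response in MCF-7 mutants, and of calls inside and outside shifted neighbourhoods were chosen only after the result was seen. A test of the difference between groups flagged the weaker response of Y537S T-47D clones to estradiol, 13 genes, all lower and CXCL12 and SUSD3 among them, or 128 with the clone as a block. The same test flagged 5 genes for D538G in T-47D, 208 for Y537S in MCF-7 and 51 for D538G in MCF-7, in each case with the clone as a block. Between the lines, the estradiol response differed for 4 genes, FLT4 (log2 difference -3.35, adjusted p = 0.0369), PFKFB3 (-2.06, 0.00195), CISH (-1.72, 0.0369) and NAB2 (1.28, 0.0369), or for 835 genes with the clone as a block. The effect of Y537S differed between the lines for 1021 genes and that of D538G for 1009. CASP14, 73.2-fold lower (12.6 to 2942) in T-47D and 659.7-fold higher (118 to 26090) in MCF-7 by counts, was among the 19 genes that Y537S moved in opposite directions in the lines, with NUPR1 (-1.69 in T-47D, 5.75 in MCF-7) and BHLHE40 (-0.75, 2.80).

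Many genes were called for each mutation in T-47D under DMSO, and some lay in stretches of neighbouring genes shifted the same way in both clones, such as 350 of 497 genes on chromosome 15 in Y537S and 420 in D538G. With every gene centred on its neighbours, 66.6% of the D538G calls and 73.5% of the Y537S calls remained, and the 2 causes, gene regulation and copy-number differences between clones, cannot be told apart for the rest because no DNA was measured. Inside shifted stretches 24.4% of the Y537S calls and 23.6% of the D538G calls remained, and outside them 78.0% and 75.4%, shares that the split itself sets, so copy number cannot be told apart from regulation in either part. An estradiol response switched on without hormone would take in 35.9% of the Y537S calls and 31.4% of the D538G calls at 8 h. It cannot be told apart from other causes, because a gene without a call at 8 h is not shown to be unchanged. Both comparisons also used the same WT DMSO libraries. Under prolonged estradiol, with the same DMSO libraries, 1709 of 2069 Y537S calls and 2205 of 3056 D538G calls moved the same way against 699 and 1036 from list sizes, and 16.8% and 27.2% of all calls did so at neither time.

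Prolonged estradiol changed 9768 genes in T-47D. Spread was pooled over groups, and the WT clones differed less at the days than at 8 h. The chi-square per gene between clones was 5.94 to 8.47 at days 5 to 20 and 22.8 at day 25. It was 57.9 under DMSO and 60.9 under estradiol for 8 h. The pooled spread may thus understate that of the 8 h groups and raise the count of calls, which was not tested. Lower depth is argued against as the cause, since 92.1% to 92.4% of the calls remained with all libraries thinned to the smallest total, and 84.7% remained after correction for GC content and length, against 49.6% in MCF-7. A response that builds up from day 5 is argued against as the whole cause by a day 25 to day 5 ratio of calls of 1.03, with 8452 genes called at day 5, although 768 genes had a slope. The difference between clones 1 and 2 had a median correlation of 0.0947 between the 8 h and day groups in T-47D, against 0.530 between DMSO and estradiol at 8 h and 0.327 between 8 h and days in MCF-7. Among the T-47D day groups themselves the median was also low, at 0.187 (0.115 to 0.240). The low value between 8 h and days is thus no sign of another stock by itself. Another cell stock or library set at 5 to 25 days cannot be told apart from a lasting hormone response, because no DMSO group was kept for those days.

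For estradiol in mutant MCF-7 clones, where GREB1 was already high under DMSO, edgeR called no gene, DESeq2 called 0 in Y537S and 2 in D538G, and leaving out 1 library gave up to 1 and 2. For the 189 genes that estradiol induced in T-47D, the median of mutant DMSO minus WT estradiol was -0.24 in Y537S and -0.22 in D538G, against a WT response of 0.65. These values fit targets already raised without hormone. A response of the WT size hidden by spread between clones is argued against by the difference of response, whose larger p over the mutants was 0.0042 with an estimated correlation, at a median difference of -0.46. How far the shared WT libraries add to these medians stays open.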

How the results depend on the processing

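Alternatives chosen only after the data were seen were the neighbour-centred, GC and length, thinned and doubted-library fits. Across 5332 checks of 400 named-gene results, 4670 kept their direction and their side of the threshold, 642 kept the direction without the call, 20 gained a call and 0 reversed. Genes named as the largest changes had to be called. In group comparisons at 8 h they also had to show no overlap between the libraries compared. For prolonged estradiol, both clones had to change in the same direction on average over the days. For genes so named the rule largely precluded a reversal in advance. The counts of called genes that follow moved by over 1.5 times, apart from those of the thinned and doubted-library fits and parts of the leave-one-out ranges, and the cause was not tested except where fewer libraries or the block itself changed the spread. The prolonged T-47D groups held the fewest counts, which can limit the smallest changes called there. For prolonged estradiol in T-47D, 90% of simulated 2-fold changes were recovered.

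DESeq2 called more genes than edgeR wherever the counts moved. In T-47D its counts against edgeR's were 677 and 253 for estradiol in WT, 19 and 0 in Y537S, 302 and 117 in D538G, 55 and 13 for the difference of response in Y537S and 7 and 0 in D538G, 1858 and 1147 for Y537S in estradiol, 2277 and 1463 for D538G in estradiol and 1950 and 768 for the trend. In MCF-7 they were 340 and 22 for estradiol in WT, 2 and 0 in D538G, 1031 and 220 for Y537S, 497 and 4 for D538G, 15 and 0 and 4 and 0 for the differences of response, 675 and 103 for Y537S and 471 and 0 for D538G in estradiol, 91 and 3 between mutants and 1318 and 333 for the trend. DESeq2's shared genes were 394 for estradiol and Y537S and 323 for estradiol and D538G in T-47D, 117, 98 and 320 for these pairs and for both mutations in MCF-7, and 165 for Y537S and 92 for D538G in both lines; the cause was not tested.

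Without the low-count filter, T-47D had 4 calls for estradiol in Y537S, 192 in D538G, 37 for the Y537S difference of response and 1 for D538G. The same setting in MCF-7 gave 85 for estradiol in WT, 407 for Y537S, 87 for D538G, 199 for Y537S and 21 for D538G in estradiol and 6 between mutants, shared genes of 24, 18 and 69 within MCF-7, and 64 for Y537S and 22 for D538G in both lines. RLE scaling in place of TMM moved only estradiol in Y537S T-47D clones, to 1 call. The cause was not tested for the filter or the scaling.

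With only the compared groups in the fit, which leaves fewer libraries to estimate spread, T-47D had 140 calls for estradiol in WT, 209 for Y537S, 8 for the Y537S difference of response, 477 for Y537S and 2950 for D538G in estradiol and 14 between mutants. MCF-7 had 0 for estradiol in WT, 19 for Y537S, 1 for D538G, 8 for Y537S in estradiol and 0 between mutants under that setting.

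The clone as a block, which pairs treatments of 1 clone, gave 2668, 86 and 868 calls for estradiol in WT, Y537S and D538G T-47D clones and 128 and 5 for the differences of response, and in MCF-7 2084 for estradiol in WT, 208 and 51 for the differences and 1121 for the trend. A further setting used the clone as a block for estradiol and only the clone number as a block for the mutations. It gave 764 and 980 genes shared by estradiol with Y537S and D538G in T-47D and 202 and 20 in MCF-7. The clone as a block moved no other count of called genes within a line by over 1.5 times. Further counts of shared genes did move. In T-47D, estradiol in D538G and Y537S under DMSO went from 83 to 338. Estradiol in Y537S and D538G under DMSO went from 0 to 20. Where genotypes share only a clone number, a block on that number gave 470 for Y537S, 33 for D538G, 211 and 24 for them in estradiol and 5 between mutants in MCF-7, and moved no T-47D count by over 1.5 times.

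Centring every gene on its chromosomal neighbours gave 814 calls for D538G in estradiol in T-47D, and 12 for D538G and 5 for D538G in estradiol in MCF-7. GC and length correction gave 2709 prolonged calls against DMSO and 2059 against 8 h in MCF-7, with 49.6% and 40.4% of the original calls among them, and 1582 slopes in T-47D. Slopes over days 5 to 20 numbered 4147 in T-47D and 725 in MCF-7. The cause was not tested for any of these. No alternative reversed a named gene, which the naming rule largely set in advance. The larger side of the calls did change in T-47D, from 206 higher and 47 lower to 1195 and 1473 for estradiol in WT with the block, from 1185 and 915 to 1368 and 1484 for Y537S without its DMSO clone 2, and from 1434 and 1684 to 763 and 596 for D538G without its DMSO clone 2. It also changed where the sides were near equal, as in the trend and prolonged comparisons, and where few genes were called in MCF-7. With no count moved by over 1.5 times, thinning the libraries to the smallest total gave 9255 and 8247 prolonged calls in T-47D and 4232 and 3878 in MCF-7, and dropping the day 5 clone 2 and day 25 clone 1 libraries of MCF-7 gave 4021, 3858 and 279 slopes.

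Leaving out 1 library at a time, the lone clone left in a group being assumed to vary like the other groups, gave these ranges in T-47D: 50 to 139 for estradiol in WT, 0 to 1 in Y537S, 9 to 31 in D538G, 781 to 2852 for Y537S, 1053 to 1644 for D538G, 4 to 16 for the Y537S and 0 to 0 for the D538G difference of response, 325 to 639 for Y537S and 215 to 556 for D538G in estradiol, 227 to 1664 between mutants, 8357 to 10066 and 6920 to 9164 for prolonged estradiol against DMSO and 8 h, and 75 to 3312 for the trend. The MCF-7 ranges in the same order were 0 to 40, 0 to 1, 0 to 2, 4 to 63, 0 to 1, 0 to 0, 0 to 0, 0 to 19, 0 to 2, 3 to 4, 903 to 4691, 1051 to 4396 and 95 to 543.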

Other observations

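The test of clone differences between 8 h and days, whose correlation was 0.0947 in T-47D, was chosen only after the result was seen. Among lists outside the estrogen response, the unfolded protein response gave 9 rising, 4 falling and 3 uncalled genes of 16 in T-47D under prolonged estradiol against DMSO (adjusted p = 0.215), and 5 rising and 11 uncalled in MCF-7 (adjusted p = 0.00623, and 0.314 with an estimated correlation), with the chaperone cofactor SDF2L1 (1.31) and CHAC1 (3.13) higher and DNAJB9 (-1.22) lower in T-47D, and SDF2L1 (1.65) and ATF3 (1.88) higher in MCF-7. Of 16 p53 targets in T-47D 9 rose, 2 fell and 5 were not called against DMSO (adjusted p = 0.259), and in MCF-7 7 rose, 2 fell and 7 were not called (adjusted p = 0.0645), with SESN2 (1.11) and FDXR (0.81) higher and TP53INP1 (-1.14) and PLK2 (-2.02) lower in T-47D, and the cyclin kinase inhibitor CDKN1A (1.36) and GDF15 (2.33) higher in MCF-7. Inflammatory NF-kB genes rose in 5 of 9 cases with 4 not called in T-47D (adjusted p = 0.229) and in 1 of 9 with 8 not called in MCF-7 (adjusted p = 0.162), with TNFAIP2 (1.85) and ICAM1 (2.30) higher in T-47D and TNFAIP2 (1.13) in MCF-7. Immediate early genes, which also respond to handling, rose in 10 of 15 cases in T-47D, fell in 1 and were not called in 4 (adjusted p = 0.0766), with FOS (5.68) and EGR1 (2.48) higher and the heat shock gene DNAJB1 (-0.78) lower. Growth factor genes rose in 11 and fell in 4 of 17 cases in T-47D with 2 not called (adjusted p = 0.204), and rose in 6 and fell in 3 with 8 not called in MCF-7 (adjusted p = 0.033, and 0.314 with an estimated correlation), with IGFBP4 (2.67) higher and ERBB2 (-1.75) and FGFR4 (-1.47) lower in T-47D, and the insulin receptor substrates IRS1 (1.24) and IRS2 (1.63) higher in MCF-7.

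Androgen, progesterone and glucocorticoid targets rose in 3 and fell in 4 of 9 cases in T-47D with 2 not called (adjusted p = 0.495), and rose in 2 and fell in 2 of 8 with 4 not called in MCF-7 (adjusted p = 0.667), with TSC22D3 lower in both (-1.86 and -1.98) and the kinase SGK1 (2.29) higher in MCF-7. Basal genes rose in 3 and fell in 3 of 9 cases in T-47D with 3 not called (adjusted p = 0.754) and rose in 5 of 14 with 9 not called in MCF-7 (adjusted p = 0.000692, and 0.314 with an estimated correlation), with LAMA3 (1.25) and EGFR (0.92) higher and TRIM29 (-2.46) and TP63 (-3.23) lower in T-47D, and LAMC2 (2.73) and KRT17 (5.12) higher in MCF-7. Of the immune and endothelial genes 2 were measured in T-47D, 1 rising and 1 not called, and 3 in MCF-7, 2 rising and 1 not called (adjusted p = 0.126), with the macrophage gene CD68 (0.54 and 1.63) higher in both and HBA1 (2.76), which shares reads with its copy HBA2 and is uncertain, in MCF-7. Cholesterol genes rose in 1 and fell in 6 of 18 cases in T-47D with 11 not called (adjusted p = 0.321) and rose in 4 and fell in 1 of 19 in MCF-7 with 14 not called (adjusted p = 0.306), with SC5D (-2.11) and NSDHL (-0.81) lower in T-47D, and DHCR7 (0.93) higher and IDI1 (-0.62) lower in MCF-7. Luminal genes rose in 5 and fell in 9 of 15 cases in T-47D with 1 not called (adjusted p = 0.215) and rose in 5 and fell in 1 with 9 not called in MCF-7 (adjusted p = 0.126), with XBP1 (1.04) higher and ELF3 (-2.09) and AR (-0.99) lower in T-47D, and the keratin KRT8 (1.04) higher and ESR1 (-1.82) lower in MCF-7. Hypoxia genes rose in 7 and fell in 8 of 18 cases in T-47D with 3 not called (adjusted p = 0.375) and rose in 4 with 14 not called in MCF-7 (adjusted p = 0.0125, and 0.456 with an estimated correlation), with EGLN3 (-3.60) and PGK1 (-1.31) lower in T-47D and BHLHE40 (3.39) and VEGFA (1.35) higher in MCF-7. Mesenchymal genes rose in 3 and fell in 4 of 9 cases in T-47D with 2 not called (adjusted p = 0.818) and rose in 2 and fell in 2 of 11 with 7 not called in MCF-7 (adjusted p = 0.801), with SNAI1 (4.08) and ACTA2 (1.43) higher and S100A4 (-2.69) lower in T-47D, and ACTA2 (1.14) higher and MMP14 (-2.04) lower in MCF-7. Receptor partners rose in 12 and fell in 2 of 17 cases in T-47D with 3 not called (adjusted p = 0.0786) and rose in 6 and fell in 1 with 10 not called in MCF-7 (adjusted p = 0.126), with NRIP1 (1.57 and 1.26) and RARA (0.64 and 1.21) higher in both.

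Few genes of the major histocompatibility region were counted: 18 of 195 region genes (9.23%) had at least 1 CPM in each line, against 54.4% of 390 flanking genes in T-47D and 55.4% in MCF-7, in the gene order of the GRCh38.p14 annotation. RING1, PPP1R10, ABCF1 and FLOT1 had 0 counts in every library. The clones of WT T-47D differed little at days 5 to 20, with a chi-square per gene of 5.94 to 8.47, against 22.8 at day 25 and 57.9 and 60.9 under DMSO and estradiol for 8 h.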
